A study of Brassica napus with 12 samples.

How the data were processed

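RNA of 12 libraries was used, from young seedlings of 2 pools of *Brassica napus* germplasm, each as control or after 24 h of full submergence, with 3 biological replicates per group. Per the labels' protocols, total RNA was extracted with Trizol, messenger RNA was isolated on oligo(dT) beads and fragmented, and libraries were sequenced in pairs on an Illumina instrument. Each sample mixed seedlings of 5 germplasm, so a replicate is a mixture and differences between germplasm within a pool were not measured. Tests between pools therefore use the spread between mixtures. They cannot ascribe a difference to resistance rather than to the germplasm that were pooled. The labels call the replicates biological.

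The authors deposited RPKM values, read numbers scaled by gene length and by the mapped reads of the library, in 1 table of 109614 genes and 12 libraries. HISAT2, a read aligner, and StringTie, a transcript assembler, are named in the submitters' processing notes; their versions, settings and roles, the genome build and the annotation are not given in the sources used here. The identifiers place 44359 genes on A chromosomes, 52562 on C chromosomes and 3998 on scaffolds, and 8695 are listed as new genes; 21106 genes were listed at 0 in every library. RPKM is not a count, so no count model was used. Reads that fit both of the near-identical copies of a gene on the A and C subgenomes can be split or lost in such values, so the level of a single copy is uncertain.

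None of the identifiers matched the reference table used here (0 matches in 123214 rows), so genes were not named. The 26 gene lists fixed before the data were examined, from fermentation to light harvesting and markers of root and seed reserve, were therefore not tested, and neither length nor sequence content was checked. Chromosome and gene order were read from the identifiers. Genes were named by a rule set before the data were examined: the 2 largest rises and the 2 largest falls in log2 change in each of the 3 main comparisons (both responses and their difference), among genes with an adjusted p under 0.05, a mean of at least 5 RPKM and, for the responses, no overlap between groups.

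Values were taken as log2(RPKM + 1) without further scaling. Genes with at least 1 RPKM in at least 3 libraries were tested, 57391 in all. Tests used limma 3.58.1 in R 4.3.3 with a trend in the prior variance, all 12 libraries in 1 fit of group means (8 residual and 3.345 prior degrees of freedom), and 2-sided p-values adjusted by Benjamini-Hochberg over the tested genes at 0.05. A fold change on this scale understates the change of weakly expressed genes. The fit was tested on simulated data with 100 changed genes of each size: for the resistant response it recovered 59% of 2-fold and 84% of 4-fold changes, and for the difference between pools 30% and 75%. The changed genes averaged about 5 RPKM or more, all others were unchanged, and the noise was independent between genes. Far more genes, 22102, were called in the real resistant response. The shares therefore do not give the power of the response tests, nor that for weaker genes. Group differences of single values used exact permutation tests. The clustering of log2 changes along the chromosomes was compared with 100000 shuffled gene orders and, as a check added after seeing the data, with other splits of the libraries and with permuted residuals. Python 3 with numpy, pandas and matplotlib was used for the shuffling and the plots.

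Depth was compared from low values: a gene with 1 read has an RPKM that depends on the depth, so ratios of the lowest values of a gene between libraries give relative depth. The 66 pairs of libraries agreed within 0.00667 log2. Relative depth was 1, 0.848 and 0.638 in resistant controls, 0.9, 0.893 and 0.936 in resistant submerged, 0.727, 0.768 and 0.786 in susceptible control and 0.738, 0.824 and 0.844 in susceptible submerged libraries. An earlier form of this estimate misread 2 libraries by a factor of 2 and was replaced. Absolute depth is unknown, so no counting intervals are given. No 2 libraries held identical values; at least 70.7% of genes differed in each pair.

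The alternatives set before the data were examined were a pseudocount of 0.1, no filter on low values, a stricter filter of a mean of 5 RPKM, quantile normalization, median ratio scaling, the replicate number as a block, only the libraries of the groups compared, and leaving out each library in turn. Added after seeing the data were the removal of co-varying windows and scaffold genes, the removal of genes that were listed at 0 in 1 replicate and at 5 RPKM or more in another of the same group, the centring of each window of 50 genes, and a recount of the genes at 1 and 10 RPKM after median ratio scaling. The window analysis, the C02 and A02 blocks, the limit of 0.3 for co-varying windows, the classes of switched and pool-specific genes, and the check on abundant genes were also chosen after seeing the data. All libraries were used.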

Results

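Gene expression was measured by sequencing of polyadenylated RNA from young seedlings of rapeseed, *Brassica napus*, an allotetraploid crop with an A and a C subgenome. Seedlings came from 2 pools of germplasm, called resistant and susceptible to submergence by the labels, and each pool mixed equal amounts of 5 germplasm. Each pool was sampled as control and after 24 h under water, with 3 biological replicates per group and 12 libraries in all. The values were RPKM for 109614 genes, of which 57391 reached the expression minimum and were tested. Absolute depth was not known; the spacing of the lowest values put the libraries between 0.638 and 1 of the depth of the deepest one, the first resistant control. The gene identifiers name a chromosome, but they are not paired with gene names in the sources used here, so genes are given by identifier and gene groups by chromosome.

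Fewer genes were at 1 RPKM or more in submerged seedlings than in controls in both pools. Genes at 1 RPKM or more numbered 54155.3 ± 372.2 (SD, n = 3) in resistant controls and 50953.7 ± 265.5 (SD, n = 3) after submergence. In the susceptible pool the number was 52849.7 ± 325.9 (SD, n = 3) in controls and 49326.3 ± 301.0 (SD, n = 3) after submergence. The mean difference over pools was -3362.5 genes (2-sided exact permutation p = 0.005 over 400 arrangements within pools; 0.006667 after Benjamini-Hochberg adjustment over 4 measures). It was -1786 for genes above 0 and -1251.67 for genes at 10 RPKM or more (exact permutation p = 0.005 for each). The median RPKM of the tested genes was also lower, 4.73 against 5.55 in the resistant and 4.42 against 5.14 in the susceptible pool. Recounted after median ratio scaling, a check added after seeing the data, the differences were -1534.67 genes at 1 RPKM or more and 1173.83 at 10 RPKM or more (2-sided exact permutation p = 0.005 for each, 0.005 after Benjamini-Hochberg adjustment over 2 measures), so the direction at 10 RPKM turned with the scaling. The share of RPKM in the 100 most abundant genes differed by -0.2052 percentage points (exact permutation p = 0.685).

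Treatment was the main axis of variation and the pool the next. The first principal component held 49.4% of the variance and separated the 6 submerged from the 6 control libraries, and the second held 22.2% and separated the pools. The median correlation of log2 values across genes was 0.962 within groups, 0.925 between pools under the same treatment and 0.875 between treatments of the same pool. Genes are not independent replicates, so these correlations describe the libraries only.

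**Figure D1:**
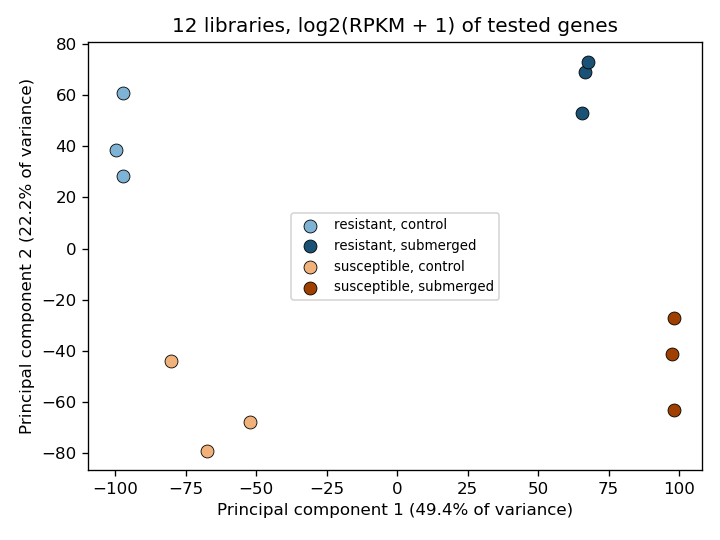
Principal components 1 and 2 of log2(RPKM + 1) over the tested genes, in component units, with 1 point per library and 1 colour per group (n = 3). Component 1 holds 49.4% of the variance and parts control from submerged libraries; component 2 holds 22.2% and parts the pools.

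In the resistant pool, submergence raised 6806 genes and lowered 15296 of the 57391 tested (limma, adjusted p under 0.05). Changes of at least 2-fold were about as frequent in both directions, 3293 higher and 3334 lower. Changes of 8-fold or more were mostly rises, 218 against 94. The gene with the largest rise was BnaC01G0499200ZS, at 0.502 ± 0.0751 RPKM (SD, n = 3) in controls and 237 ± 58.6 (SD, n = 3) after submergence, a log2 change of 7.28 ± 0.16 (SE; limma adjusted p = 1.61e-09). BnaC04G0163500ZS rose from 1.65 ± 1.02 to 271 ± 70.7 RPKM (SD, n = 3; limma adjusted p = 2.15e-07). The largest falls were in transcripts that the file lists as new genes. Brassica_napus_newGene_3264 fell from 78.4 ± 18.5 to 0.697 ± 0.209 RPKM (SD, n = 3; limma adjusted p = 1.95e-06), and Brassica_napus_newGene_10565 from 51.3 ± 7.94 to 0.197 ± 0.0899 RPKM (SD, n = 3; limma adjusted p = 2.19e-06). The median log2 change of all tested genes was -0.22. Counted relative to that median, 4315 genes were at least 2-fold higher and 1939 lower, and the share of calls that were rises went from 30.8% to 48.4% with quantile normalization (8808 higher, 9400 lower), 52.1% with median ratio scaling (9624 higher, 8839 lower) and 52.2% with window centring (9394 higher, 8603 lower), which was chosen after seeing the data.

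The susceptible pool responded with similar numbers, 6903 genes higher and 16399 lower (limma, adjusted p under 0.05), of which 3346 and 3645 changed by at least 2-fold. BnaC01G0499200ZS again rose most, from 1.31 ± 0.239 to 213 ± 8.59 RPKM (SD, n = 3), a log2 change of 6.54 ± 0.16 (SE; limma adjusted p = 5.41e-09). BnaA03G0373800ZS rose from 0.376 ± 0.133 to 99.2 ± 75.7 RPKM (SD, n = 3; limma adjusted p = 2.58e-06). BnaC02G0174800ZS fell from 37.2 ± 28.1 to 0.238 ± 0.206 RPKM (SD, n = 3; limma adjusted p = 3.81e-05). BnaC05G0503500ZS was at 34.3, 31.3 and 26.1 RPKM in the susceptible controls and listed at 0 in all 3 submerged libraries (limma adjusted p = 0.0154). It was also listed at 0 in 3 of the 6 resistant libraries, so its fall lies within the spread between replicates seen in the other pool. The median log2 change of all tested genes was -0.19. Relative to it, 4254 genes were at least 2-fold higher and 2332 lower, and the share of calls that were rises went from 29.6% to 46.0% with quantile normalization (8591 higher, 10069 lower), 51.5% with median ratio scaling (10341 higher, 9748 lower) and 51.8% with window centring (9471 higher, 8800 lower).

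Most of the response was shared by the pools. Of the tested genes, 4942 were higher in both pools, against 818.6 for independent lists, and 10606 were lower in both, against 4370.7. The shared falls numbered 5777 with quantile normalization, 5427 with median ratio scaling and 5210 with window centring. Only 80 genes were called in opposite directions, and 46 without the third resistant control or the first resistant submerged library and 52 without the third resistant submerged library. Across genes, the log2 changes of the pools correlated with Pearson's r = 0.81 and Spearman's rho = 0.71; the pools share no control library. A further 6474 genes were called in the resistant pool only and 7674 in the susceptible pool only, and the estimate in the other pool had the same sign for 85.1% and 85.6% of them. The shares of signs over all tested genes alone would give 57.2% and 58.8%, and relative to the median change the same sign was found for 71.6% and 64.7%. Of these genes, 65 and 48 genes had a response that differed between pools by the interaction test.

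A response that differed between pools was called for 191 genes (limma, adjusted p under 0.05), 110 with a higher change in the resistant pool and 81 with a lower one, and 7472 genes had an unadjusted p under 0.05. Among the 110, the median log2 change was 1.49 in the resistant and -0.25 in the susceptible pool; 36 rose in the resistant pool without a call in the susceptible one, 28 rose in both, 26 fell in the susceptible pool without a call in the resistant one and 15 rose in the resistant and fell in the susceptible pool. Among the 81, the medians were -0.75 and 0.63, with 29 falling in the resistant pool alone by call, 22 rising in the susceptible pool alone by call and 16 doing both. Pool differences were called for 73 of the 110 and 63 of the 81 genes in controls and for 62 and 47 in submerged seedlings, against 15.9% and 16.4% of all tested genes; these libraries also enter the interaction, which raises such shares by itself. BnaC04G0595200ZS had the largest positive difference, at 14.4 ± 6.73 RPKM in resistant controls and 83.4 ± 50.3 after submergence, against 95.9 ± 28.7 and 36.0 ± 16.5 in the susceptible pool (SD, n = 3; log2 difference 3.83 ± 0.63, SE; limma adjusted p = 0.0358). BnaA03G0312700ZS went from 2.03 ± 0.719 to 62.4 ± 21.3 RPKM in the resistant pool and from 13.4 ± 1.83 to 30.4 ± 5.66 in the susceptible one (SD, n = 3; log2 difference 3.25 ± 0.37, SE; limma adjusted p = 0.00898). BnaC02G0049800ZS stood at 48.0 ± 27.3 and 52.6 ± 14.4 RPKM in the resistant pool and rose from 5.86 ± 0.908 to 94.7 ± 23.5 in the susceptible pool (SD, n = 3; log2 difference -3.50 ± 0.56, SE; limma adjusted p = 0.0338). It is number 255 in the order of tested genes on C02. It thus lies within the first 500 compared below, whose mean level was also lower in susceptible than in resistant controls. BnaC03G0034300ZS fell from 39.4 ± 27.7 to 6.16 ± 1.73 RPKM in the resistant pool and stood at 20.3 ± 4.84 and 35.1 ± 3.60 in the susceptible one (SD, n = 3; log2 difference -3.10 ± 0.53, SE; limma adjusted p = 0.0381). The counts depended on single libraries: leaving out any 1 of the 12 moved the count above 0 by over 1.5 times, to between 10 and 210 genes, and gave 8 to 133 below, with the lowest counts without the first and the highest without the second susceptible control. In simulated data, where only genes averaging about 5 RPKM or more were changed, the test recovered 30% of 2-fold and 75% of 4-fold differences. BnaA03G0312700ZS passed the threshold in all 21 alternatives, whereas the other 3 genes each lost the call in 10 to 12 of them. With the replicate number as a block, 23 genes above and 18 below 0 were called, and 40 of the 191 calls were kept.

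**Figure D2:**
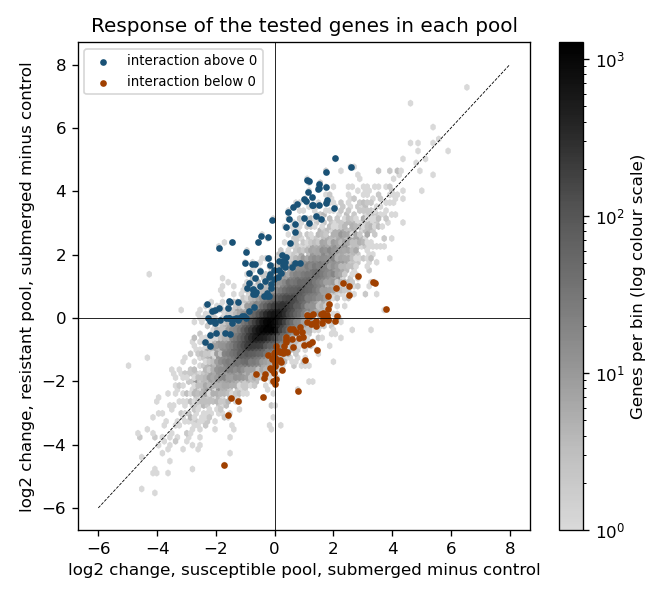
Log2 change after submergence in the susceptible pool (horizontal axis) against the resistant pool (vertical axis) for the tested genes, as shaded bins with a log colour scale; the dashed line marks equal change. Coloured points are the 110 genes with a higher and the 81 with a lower change in the resistant pool by the interaction test, and most other genes lie along the line (Pearson's r = 0.81 across genes).

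Between the pools under control conditions, 6268 genes were higher and 2879 lower in the resistant pool (limma, adjusted p under 0.05), 1706 and 1186 of them by at least 2-fold. The differences were unevenly spread over the chromosomes. On C02, 21.2% of tested genes were higher in the resistant pool and 3.61% lower, followed by C06 with 16.2% and 3.55%, A03 with 14.2% and 4.77% and C09 with 13.7% and 3.53%; C08 had the lowest share of higher genes, 6.76%. Neighbouring genes often shared the call, with 20.2% of called genes followed by a gene called in the same direction against 8.85% for random order. The split moved with the scaling, from 68.5% of calls higher to 56.5% with quantile normalization (4938 higher, 3798 lower), 55.8% with median ratio scaling (4501 higher, 3568 lower) and 49.7% with window centring (3279 higher, 3314 lower). Without the first resistant control there were 3734 higher and 1790 lower genes, without the first susceptible control 3691 and 1863, and the lower genes numbered 1725 without the third resistant and 1919 without the second susceptible control.

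After submergence, 6736 genes were higher and 2681 lower in the resistant pool (limma, adjusted p under 0.05), 1588 and 922 of them by at least 2-fold. A03 (17.4%) and C02 (17.3%) had the highest shares of genes higher in the resistant pool. Between the control and the submerged comparison, 2899 higher and 1132 lower genes were shared, against 735.7 and 134.5 for independent lists, and 45 genes were called in opposite directions. The share of calls that were higher went from 71.5% to 61.1% with quantile normalization (4578 higher, 2911 lower), 55.4% with median ratio scaling (4926 higher, 3969 lower) and 50% with window centring (3553 each way). Higher and lower genes numbered 3684 and 1413 without the first, 4123 and 1537 without the second and 3447 and 1472 without the third resistant submerged library, and 3686 and 1595 without the first susceptible submerged library.

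**Figure D3:**
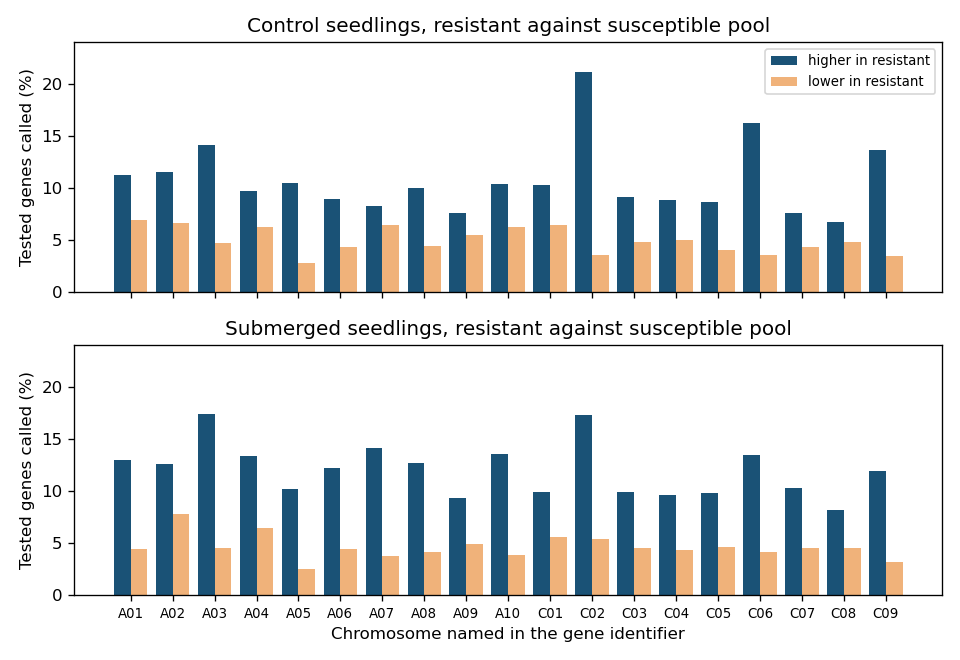
Percent of tested genes on each chromosome called higher (blue) or lower (orange) in the resistant than in the susceptible pool, in control (top) and submerged seedlings (bottom), from 3 libraries per group. C02 has the highest share of higher genes in controls, 21.2%, and A03 and C02 have 17.4% and 17.3% after submergence.

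Shares of called genes were compared between the subgenomes. In the resistant pool, 12.1% of A and 12.6% of C genes rose, and 25.5% of A and 28.6% of C genes fell, a difference in falls of 3.10 percentage points (95% interval over genes by the normal approximation, 2.34 to 3.86). It was 1.23 without the co-varying windows, 1.299 with window centring, 1.44 without a filter, 1.94 with quantile normalization and 1.96 with median ratio scaling. In the susceptible pool, 11.6% of A and 13.3% of C genes rose, a difference of 1.66 points (1.099 to 2.23). It was 0.734 without a filter, 0.878 without the co-varying windows, 0.919 with window centring, 1.00 with only the groups compared, 2.80 with the stricter filter and 2.99 with median ratio scaling. For falls, 29.8% and 29.0%, the difference was -0.85 points (-1.63 to -0.07), but -3.04 without the co-varying windows, -0.047 without the second susceptible submerged library, 0.219 with the stricter filter and 1.25 with window centring. Of the 38 co-varying windows, 17 lay on A05, 13 on A09, 4 on A06 and 2 on A01, against 1 each on C01 and C08. Of their 1900 genes, only 40 were called in the resistant and 35 in the susceptible response. These windows therefore lowered the A shares more than the C shares. The intervals take genes as independent, and cover neither the correlation between genes nor the spread between replicates. Of genes on unplaced scaffolds, 4.69% were called higher and 6.47% lower in the resistant pool and 4.82% and 7.33% in the susceptible pool; the difference from other genes was not tested.

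Log2 changes were compared along the chromosomes. The SD of the mean log2 change over 1037 windows of 50 neighbouring genes was 0.150 in the susceptible and 0.133 in the resistant pool, against 0.102 for shuffled gene order in both (permutation p = 1e-05, the smallest that 100000 permutations can give). For the difference between pools it was 0.136 against 0.0613 (permutation p = 1e-05). Shuffling takes neighbouring genes as independent, and genes in 38 windows varied together between replicates, so these p-values do not separate a response from variation between libraries. Other splits of the 6 libraries gave up to 0.178 in the resistant and 0.1499 in the susceptible pool, and 20 of 100 permutations of residuals, the real order included, gave as large a value for the difference between pools. Without those windows, which lowers the other splits by construction, the SD was 0.125 in the resistant pool, 0.152 in the susceptible pool and 0.118 for the difference, and the highest others were 0.0641, 0.0881 and 0.109. Over the first 500 tested genes of C02, relative to the library median, the susceptible pool shifted by 0.33 ± 0.08 (SE, n = 3) and the resistant pool by 0.016 ± 0.063 (SE, n = 3). Over the first 500 of A02, the susceptible pool shifted by -0.18 ± 0.02 (SE, n = 3) and the resistant pool by 0.086 ± 0.053 (SE, n = 3). The difference between pools was 0.32 for C02 (2-sided exact permutation p = 0.06; 0.06 after Benjamini-Hochberg adjustment) and -0.27 for A02 (p = 0.015; adjusted 0.03). Control and submerged names were permuted within each pool, so these p-values refer to no shift in either pool, not to equal shifts. The blocks were chosen from the window values, so these p-values are too small, and within 1 pool 3 against 3 libraries cannot give an exact p below 0.1. The C02 block stood at -0.257 in susceptible and 0.169 in resistant controls, and at 0.0745 and 0.185 after submergence. The A02 block stood at 0.402 and 0.159 in controls, and at 0.223 and 0.245 after submergence. The pools thus differed already in controls, in opposite directions on the 2 blocks, so the shifts cannot be read as a response to submergence alone.

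**Figure D4:**
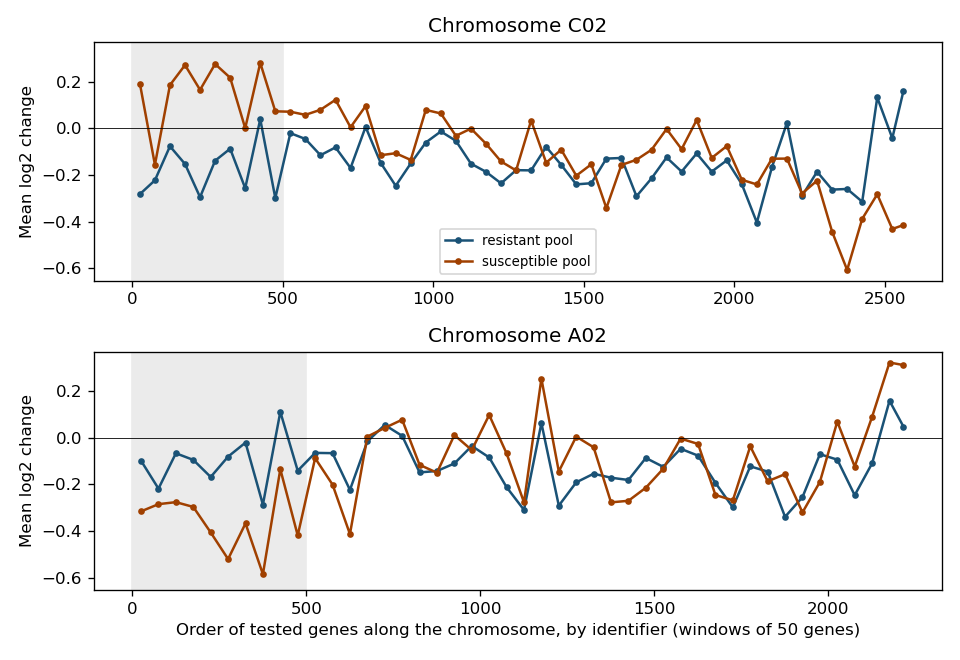
Mean log2 change after submergence in windows of 50 tested genes along C02 (top) and A02 (bottom), ordered by identifier, for the resistant (blue) and susceptible pool (orange); the shaded part holds the first 500 tested genes. There the pools lie apart, with the susceptible pool above the resistant one in most C02 windows and below it in the A02 windows.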

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

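The tests of abundant genes, of the depth of submerged libraries, of a shared regional response, of 1 deviating library, of pool make-up and of depth in the co-varying windows were chosen after the result was seen, as was the permutation of residuals.

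The number of genes whose response differed between pools, 191, was picked out by the interaction test, as were BnaC04G0595200ZS (log2 difference 3.83), BnaA03G0312700ZS (3.25), BnaC02G0049800ZS (-3.50) and BnaC03G0034300ZS (-3.10). When pool names were exchanged among libraries of the same treatment, 6 of 100 arrangements, the real one included, gave 191 or more genes, and the highest of the others gave 4354, so chance could not be excluded. The 5 other arrangements that reached it gave 275 to 4354 genes. An uneven exchange moves part of the difference between pools into the interaction, a structure of the samples. Of 6 arrangements in which the numbers of libraries exchanged in the 2 treatments differed by 2, 4 reached the real count, against 1 of 54 that differed by 1 and 0 of 39 with equal numbers. When instead the residuals of a fit with pool and treatment were permuted over the libraries, 1 of 100 arrangements, the real one, gave as many, and the highest of the others gave 2. The exchange was set first and the residual check was added because of its result, so the number of genes is open until more libraries are measured. More libraries of these 2 pools would not show whether the genes go with resistance or with the germplasm that were pooled.

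For the 4 other comparisons, 1 of 10 splits of the 6 libraries, the real one, gave as many genes in each case, which is too few splits for a share under 0.05. The real counts and the highest of the other splits were 22102 and 3 for the resistant response, 23302 and 2 for the susceptible response, 9147 and 5 between controls, and 9417 and 1 between submerged pools.

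More genes fell than rose after submergence in both pools. A few abundant genes taking more of the reads are argued against by the share of RPKM in the 100 most abundant genes, which changed by -0.2052 points where a rise of 5 was needed. RPKM is scaled by gene length, so this is not a share of reads. It does not cover a rise spread over more genes. Lower depth of the submerged libraries is argued against as well, since their log2 relative depth was 0.07493 above that of controls in the susceptible and 0.1585 in the resistant pool. Among 17856 genes with a mean of at least 10 RPKM the median log2 change was -0.12 in the resistant and -0.07444 in the susceptible pool. These lie 1 on each side of the limit of -0.1, so a stronger loss among weakly expressed genes stays open, though lower depth as its source is argued against by the depths above. Among genes with a mean of at least 5 RPKM, falls still outnumbered rises, 7293 to 4774 in the resistant and 7786 to 4743 in the susceptible pool. The excess of falls was thus not confined to weaker genes. Median ratio scaling centres the genes by construction and cannot decide. RPKM values are relative to the mapped reads of each library, so they cannot show or exclude a fall of most transcripts under water, which stays open too.

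Relative to the library median, the mean over the first 500 tested genes shifted by 0.33 on C02 and -0.18 on A02 in the susceptible pool, where 110 and 44 of the genes were called higher and 56 and 228 lower. In controls, 209 of the C02 genes were called higher and 6 lower in the resistant than in the susceptible pool, and 14 and 48 of the A02 genes, so the pools differed there without submergence as well. The A02 difference between pools in the shift, -0.27, was picked out by its exact permutation p of 0.015, and that of C02 had p = 0.06. Both p-values refer to no shift in either pool, not to equal shifts. A single deviating library is argued against, since the C02 shift in the susceptible pool was at least 0.257 without any 1 of the 6 susceptible libraries, and the A02 difference between pools lay between -0.295 and -0.228 without any 1 of the 12. A different make-up of the mixed seedlings at segments that A02 and C02 share may be involved; within groups the blocks correlated with r = -0.3541 (exact permutation p = 0.304) and rho = -0.46 (exact permutation p = 0.2106), and r = -0.12 without the 2 farthest libraries, so this cannot be told apart from other causes with 12 libraries. A regional response, in the susceptible pool alone or common to both pools, stays open as well. In the resistant pool the shift was 0.01622 on C02 and 0.086 on A02, the latter opposite in sign to the susceptible pool. There, 60 of the C02 genes were called higher and 142 lower, and 68 and 115 of the A02 genes. The blocks were picked from window values where the pools differed, so these values do not decide it.

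In 38 windows holding 1900 genes, mostly on A05 (17 windows) and A09 (13), picked for an SD between replicates over 0.3 log2, the median window SD was 0.543, against 0.0548 in other windows as the choice requires, and genes on different chromosomes correlated with a median r of 0.91 against 0.025. Sequence shared by many gene copies was predicted to bring the genes to similar levels. The spread of levels within windows was 0.7583 of that in other windows, where less than 0.5 was needed, so the prediction was not met. Genes that share only part of their sequence can differ in level, so this test cannot decide and shared sequence stays open. The block was lower in deeper libraries (within groups r = -0.7008, exact permutation p = 0.0347, 0.0694 after Benjamini-Hochberg adjustment over 2 relations; rho = -0.62, p = 0.1111; r = -0.59 without the 2 farthest). The unadjusted p met the limit of 0.05 first written; the adjusted p was taken as the limit only after this value was seen, and the depth estimate had been revised after a first result with a weaker correlation, so depth cannot be told apart from chance. Of these genes, 40, 35 and 0 were called in the resistant response, the susceptible response and their difference; without them and the scaffold genes the difference had 157 genes above and 100 below 0, and no biological explanation was tested.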

How the results depend on the processing

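The removal of co-varying windows, the removal of genes listed at 0 in single replicates and window centring were chosen after seeing the data. The 8 calls on genes named for the responses held in all 125 checks that tested the gene, while those for the difference between pools were lost in 33 of 84, with no change of sign. BnaC05G0503500ZS, with a limma adjusted p of up to 0.0435, was itself removed with the genes listed at 0 in single replicates. That check was therefore not made for it, nor was window centring for the new genes, which have no chromosome. Of 128 gene counts under other settings, 101 stayed within 1.5 times, and of 108 counts with 1 library left out, 68 did. With the stricter filter, where fewer genes were tested, falls numbered 7293 in the resistant and 7786 in the susceptible pool, 5264 genes fell in both and 40 moved in opposite directions; the difference between pools had 63 genes above and 44 below 0, and genes higher and lower in the resistant pool numbered 2606 and 1559 in controls and 2995 and 1454 after submergence. Falls in the resistant pool, the susceptible pool and both were 9400, 10069 and 5777 with quantile normalization, 8839, 9748 and 5427 with median ratio scaling and 8603, 8800 and 5210 with window centring, each of which moves the centre of the genes by construction. Window centring also gave 3279 genes higher and 3314 lower in the resistant pool in controls and 3553 each way after submergence, 49.7% and 50% of calls higher. With only the groups compared, with fewer libraries in the fit, control differences numbered 4085 higher and 1824 lower, and 53 genes moved in opposite directions. A pseudocount of 0.1 left 47 genes below 0 in the difference between pools; the cause was not tested. With the replicate block, the difference between pools had 23 genes above and 18 below 0, with 40 of the 191 calls kept and the calls of 3 of the 4 named genes lost, and no other count moved by over 1.5 times. The labels do not say whether replicate numbers mark a batch. Of 18 same-numbered pairs, 5 correlated above 0.1 (range -0.34 to 0.39), and 4 of 12 libraries correlated best with their own number. These correlations also carry the co-varying windows, so they do not settle whether the numbers pair the samples. Leaving out 1 library gave ranges of 10 to 210 and 8 to 133 (difference between pools, above and below 0), 3691 to 6672 and 1725 to 3373 (controls, higher and lower in the resistant pool), 3447 to 5633 and 1413 to 2239 (submerged), and 46 to 92 (opposite directions). The difference between C and A genes in the share of rises in the resistant pool, 0.49 points with an interval that includes 0, was 1.62 with the stricter filter, -0.503 without the co-varying windows and 1.06 with window centring. This difference was 0.030 without a filter, 0.814 with quantile normalization, 0.835 with median ratio scaling and 0.122 to 0.498 when leaving out 1 library. For falls it was 1.44 without a filter, 1.94 with quantile normalization, 1.96 with median ratio scaling, 1.23 without the co-varying windows, 1.299 with window centring and 2.17 to 2.82 when leaving out 1 library. For rises in the susceptible pool it was 0.734 without a filter, 2.80 with the stricter filter, 2.99 with median ratio scaling, 1.00 with only the groups compared, 0.878 without the co-varying windows and 0.919 with window centring. For falls it turned positive with the stricter filter (0.219) and window centring (1.25) and ranged from -0.912 to -0.047 when leaving out 1 library, and the cause was not tested. It was -3.04 without the co-varying windows. These lay mostly on A chromosomes and held few called genes, so their removal raises the A share more than the C share. Depth is known only in relative terms, so its effect on weakly expressed genes was not measured.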

Other observations

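The classes below, and the chromosome ends, were chosen after seeing the data.

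A small set of genes was switched on by submergence. Genes below 1 RPKM in all 3 controls and at 10 RPKM or more in all 3 submerged libraries numbered 37 in the resistant and 24 in the susceptible pool, and 13 were in both sets, against 0.02 for independent sets among the 57391 tested genes. Only genes below 1 RPKM in the controls can enter a set, so 0.02 is too low a value for comparison. The reverse class held 7 and 6 genes with 1 in both. By separate limits for expression in 1 pool alone, 16 genes were at 5 RPKM or more in all 6 resistant and below 0.5 in all 6 susceptible libraries, and 3 the other way round. Of the 16, 10 were on C and 3 on A chromosomes. Among 200 splits of the libraries balanced for treatment, only the real one gave 19 such genes, and the highest of the others gave 1. None of the 19 can qualify under a split that mixes the pools, so low counts in the other splits were partly built in and add little support.

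The far ends of the same chromosomes were also compared. The last 250 tested genes of C02 shifted by -0.27 ± 0.12 (SE, n = 3) in the susceptible and 0.074 ± 0.029 (SE, n = 3) in the resistant pool (difference -0.35, exact permutation p = 0.025, 0.05 after Benjamini-Hochberg adjustment). The last 250 of A02 shifted by 0.28 ± 0.06 (SE, n = 3) and 0.13 ± 0.03 (SE, n = 3), a difference of 0.15 (exact permutation p = 0.345). Here too, treatment names were permuted within each pool, so the p-values refer to no shift in either pool. In 147 genes a replicate was listed at 0 while another of the same group was at 5 RPKM or more; 82 of them were on A and 34 on C chromosomes, and 45 lay in the co-varying windows.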
